A study of Mus musculus with 6 samples.

How the data were processed

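Gene expression was measured by RNA-seq in 6 libraries of spheroids grown from 4T1, a mouse triple-negative breast cancer cell line. Per the labels, 3 libraries came from wild-type (WT) cells and 3 from a LATS1/2 double-knockout (dKO) line. The labels call the 3 libraries of each group biological replicates and do not say whether they came from separate cultures or clones, so the p-values measure the spread between these samples, which may be technical.

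The deposited values were estimated counts per gene for 48820 Ensembl mouse gene identifiers, given by the authors as whole numbers without normalization. Per the submitters' processing notes, HISAT2 2.2.1 and StringTie 2.2.1 were used with the genome build GRCm38 (mm10). The step that made counts per gene, the annotation release and the use of strand are not given in the sources used here. The estimated counts deposited by sample equalled the columns of the deposited series table in all 6 libraries. The values piled up at exactly 4, with 678 to 775 genes at 4 counts per library against 273 to 367 genes at 5. A single read pair may therefore add up to 4 counts, and a floor of 12 counts per library, or 3 read pairs, was used for genes at 0. This floor was set after the values were seen, covers counting error only, and corresponds to 0.242 to 0.314 CPM (the count of a gene scaled to the total of its library) per library. Total counts ran from 38194478 to 49630116 per library.

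Symbols and positions came from GENCODE mouse release M21, on the same build, which matched 48058 of the 48820 identifiers. The 762 unmatched identifiers held 0.0293% of the counts and were kept under their identifiers. Without strand, reads from a gene and an overlapping partner on the other strand cannot be told apart, and reads of near-identical copies can be split between them. Of the genes named, Lats2, Ccn2, Lama3, Gins2, Mvd, Mthfd2 and Gsn overlap annotated genes, besides those given as such with their values.

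Differences between the libraries labelled dKO and WT were tested with edgeR 4.0.16 in R 4.3.3. The fit used TMM normalization, the filterByExpr filter by group, robust quasi-likelihood dispersions and the quasi-likelihood F-test, with genotype as the only term. Of the listed genes, 15807 passed the filter and were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM with TMM scaling, given as the mean ± SD of 3 libraries, and fold changes are log2 values, labelled dKO minus WT, ± SE. The SE is approximate: it was derived as the absolute log2 fold change divided by the square root of the F statistic. A fold against a group with every library at 0 was computed against the floor and is a lower bound.

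Before the data were examined, 21 gene lists, the tests and the rule for named genes were fixed. The lists covered YAP/TAZ target genes, Hippo pathway components, integrin subunits, focal adhesion components, actomyosin contractility genes, extracellular matrix proteins, matrix-remodelling enzymes and inhibitors, fibroblast-acting secreted factors, chemokines and colony-stimulating factors, interferon-stimulated genes, cell cycle genes, hypoxia and glycolysis genes, epithelial genes, mesenchymal genes, cholesterol synthesis genes, and amino acid and unfolded protein stress genes. Another 5 lists held fibroblast, leukocyte and endothelial markers, mitochondrially encoded mRNAs and ribosomal protein genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, which compares a list with the other genes, with Benjamini-Hochberg adjustment over the 20 lists that had at least 5 tested members. Camera with an estimated correlation and fry, which tests a list on its own, were alternatives.

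The rule named Lats1 and Lats2, then Ccn1, Ccn2 and Ankrd1 whatever their result. It added the 6 largest rises and 6 largest falls in fitted log2 fold change among called genes with non-overlapping ranges, a mean of at least 5 CPM in the higher group and an assigned gene name. It also took the 2 members with the smallest adjusted p in each biology list, 3 for integrins and YAP/TAZ targets, and 1 member of each other list. Genes named outside the rule are given as such, and 1 gene that the rule takes is not reported here.

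On simulated counts for the same comparison, with 14910 genes tested, the test recovered 49.25% of 67 genes changed 1.5-fold, 68.66% of 67 changed 2-fold and 95.38% of 65 changed 4-fold. It called 147 genes, of which 6 had been simulated without a change, and it called the 1 list simulated with a rise among 20 lists. Genes were simulated independently, and in the gene test only a small set of well-counted genes was changed. The simulation therefore says nothing about lists whose members move together. It also does not give the recovery at low counts or with as many changed genes as were called here. The alternatives fixed in advance were other normalizations, count filters, thresholds, list tests, a replicate block, DESeq2 1.42.0, and leaving out each library in turn. Counts divided by 4, a correction for GC content and transcript length, and a fit without WT 2 and dKO 3 were added after the data were seen.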

Results

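The data describe spheroids of 4T1 cells, a mouse triple-negative breast cancer line, and ask how expression differs when LATS1 and LATS2, the kinases of the Hippo pathway that restrain the coactivators YAP and TAZ, are knocked out. The title of the study points to integrins, to forces generated by tumour cells and to neighbouring fibroblasts, so genes of these groups were followed. Expression was compared between 3 WT libraries, with totals of 49630116, 40150225 and 47034617 counts, and 3 libraries labelled dKO, with totals of 38194478, 40667902 and 42486146 counts.

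Lats1 (ENSMUSG00000040021, GRCm38 chromosome 10, 7681214 to 7716460) was lower in all 3 libraries labelled dKO, at 50.9 ± 2.55 CPM against 153 ± 6.36 CPM in WT (SD, n = 3). Its log2 fold change was -1.59 ± 0.07 (SE, edgeR adjusted p = 4.66e-07). Lats2 (ENSMUSG00000021959, chromosome 14, 57689662 to 57758388) was not lower but higher in all 3 libraries labelled dKO, at 77.9 ± 12.5 CPM against 27.2 ± 4.01 CPM in WT. The log2 fold change of Lats2 was 1.52 ± 0.15 (edgeR adjusted p = 3.46e-05). Counts per gene do not show small insertions or deletions, so the Lats2 level does not check the knockout, and every direction below is between libraries as labelled. Lats2 also overlaps the annotated genes Gm49361 on its strand and Gm20430 and Gm26440 on the other.

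YAP/TAZ target genes were higher in the libraries labelled dKO. Ccn2, which encodes a secreted matricellular protein, rose from 19.8 ± 1.02 to 379 ± 17.5 CPM, a log2 fold change of 4.26 ± 0.08 (edgeR adjusted p = 8.96e-09). Amotl2, which encodes a YAP-binding angiomotin, rose from 34.5 ± 1.95 to 934 ± 119 CPM, and Gadd45b, a stress-response gene, rose by 3.76 ± 0.13 on the log2 scale. Ccn1, which encodes a matricellular protein related to that of Ccn2, rose by 4.56 ± 0.63, and Ankrd1, an ankyrin-repeat gene, by 2.33 ± 0.16 (edgeR adjusted p = 0.00234 and 4.47e-06). Ccn1 varied within groups, with 64.2 CPM in WT 2 against 26.0 and 18.6 CPM in WT 1 and WT 3, and 563 CPM in dKO 3 against 1000.3 and 1000.8 CPM in the others, and its log2 fold change was 5.26 without WT 2. Of 17 tested members, 12 rose, 3 fell and 2 did not pass, with a median log2 fold change of 1.23. The list differed from other genes by camera (adjusted p = 2.69e-09), and also with an estimated correlation (adjusted p = 0.0487 with an estimated correlation).

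**Figure D1:**
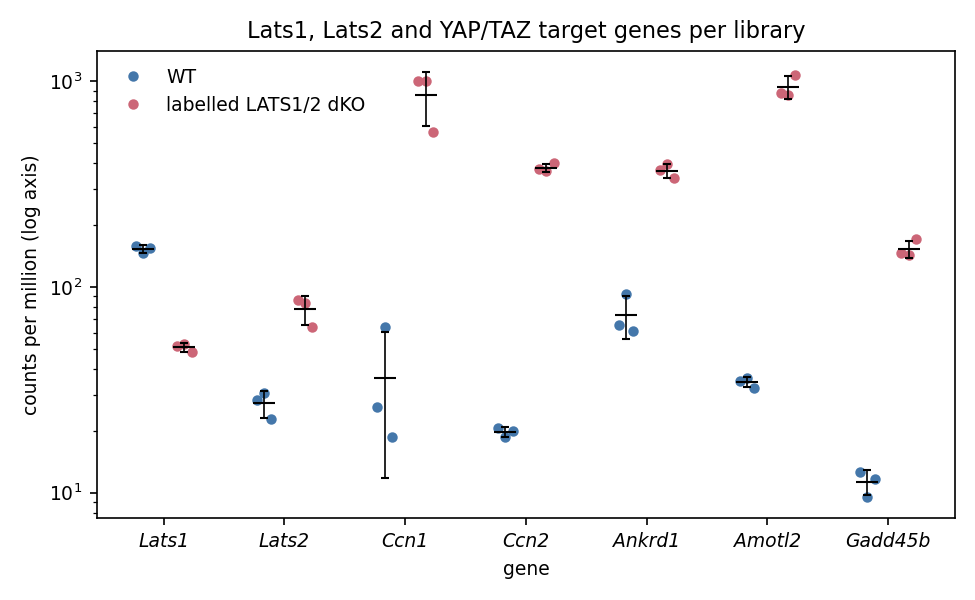
Levels of Lats1, Lats2 and 5 YAP/TAZ target genes in each library, in CPM on a log axis; points are libraries, and bars are the mean and SD of 3 WT or 3 libraries labelled dKO. Lats1 is lower in the libraries labelled dKO (50.9 against 153 CPM), while Lats2 (77.9 against 27.2 CPM) and the 5 target genes are higher.

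Across all genes, 9060 of 15807 tested genes (57.32%) were called, 4526 higher and 4534 lower in the libraries labelled dKO. At least 2-fold changes were fitted for 1915 of the higher and 2213 of the lower genes. The ranges of the groups did not overlap for 8953 of the called genes and for 10375 of the tested genes, where chance gives 10% for 3 against 3. The first principal component separated the groups and held 82.01% of the variance, while WT 2 and dKO 3 lay apart from the other libraries of their groups. Tested against a 1.5-fold change rather than no change, 4556 genes were called.

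The 6 largest fitted rises and the 6 largest fitted falls taken by the naming rule were all in genes at 0 in every library of 1 group, so their folds are lower bounds and do not rank them against genes detected in both groups. In the libraries labelled dKO, Palm3, a paralemmin family gene, reached 91.4 ± 10.3 CPM with 0 counts in every WT library, at least 343-fold higher. Mrgprb2, a mast cell receptor gene, was at least 144-fold higher and Serpinb9b, a serpin gene, at least 95.6-fold higher. Siglecg, a sialic acid-binding lectin gene, was at least 93.2-fold, Fras1, a basement membrane protein gene, at least 89.9-fold, and Gc, the vitamin D-binding protein gene, at least 59.99-fold higher. Conversely Eya2, a transcriptional coactivator gene, stood at 151 ± 3.55 CPM in WT and at 0 in every library labelled dKO, at least 511-fold lower. Csgalnact1, a chondroitin sulfate synthesis gene, was at least 203-fold lower, Slfn2, a schlafen gene, at least 197-fold, and Dio2, which encodes a deiodinase that activates thyroid hormone, at least 157-fold. Egln3, a prolyl hydroxylase gene, was at least 114-fold and Siglec15 at least 73.9-fold lower. The edgeR adjusted p of these 12 genes was 1.32e-06 or smaller. Mrgprb2, Serpinb9b, Siglecg, Siglec15 and Slfn2 belong to families of similar genes, and Palm3, Serpinb9b, Fras1, Eya2, Csgalnact1, Slfn2 and Dio2 overlap other annotated genes, so read assignment there is uncertain.

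Among Hippo pathway components, Nf2, the gene of the upstream regulator merlin, rose from 147 ± 6.40 to 485 ± 28.4 CPM, and Wwc1, which encodes the upstream regulator KIBRA, rose from 109.6 ± 7.74 to 375 ± 15.5 CPM (edgeR adjusted p = 2.65e-07 and 2.79e-07). Of 24 members, 9 rose, 10 fell and 5 did not pass, and the list as a whole did not pass (camera adjusted p = 0.497).

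Integrin subunit genes were mostly lower among those that changed. Itga3, the alpha subunit of a laminin receptor, fell from 1568 ± 30.9 to 659.9 ± 17.9 CPM, a log2 fold change of -1.25 ± 0.06 (edgeR adjusted p = 6.8e-07). Itga8 was at 16.95 ± 0.994 CPM in WT and at 0 in every library labelled dKO, at least 57.2-fold lower, and it overlaps Gm37701 and E030013I19Rik. Itgb6, the beta subunit of a receptor that activates latent TGF-beta, rose from 0.798 ± 0.425 to 28.5 ± 2.05 CPM, a log2 fold change of 5.17 ± 0.33 (edgeR adjusted p = 2.91e-06). Itgb1, the shared beta subunit, named after its values were seen, was at 1157 CPM in WT and 1189 CPM in the libraries labelled dKO and did not pass (edgeR adjusted p = 0.711). Of 18 tested subunits, 9 fell, 3 rose and 6 did not pass, with a median log2 fold change of -0.77. The list did not pass (camera adjusted p = 0.098), and it passed with a stricter count filter (0.0381) and without WT 2 and dKO 3 (0.00901), within a range of 0.00901 to 0.327 over the camera alternatives.

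**Figure D2:**
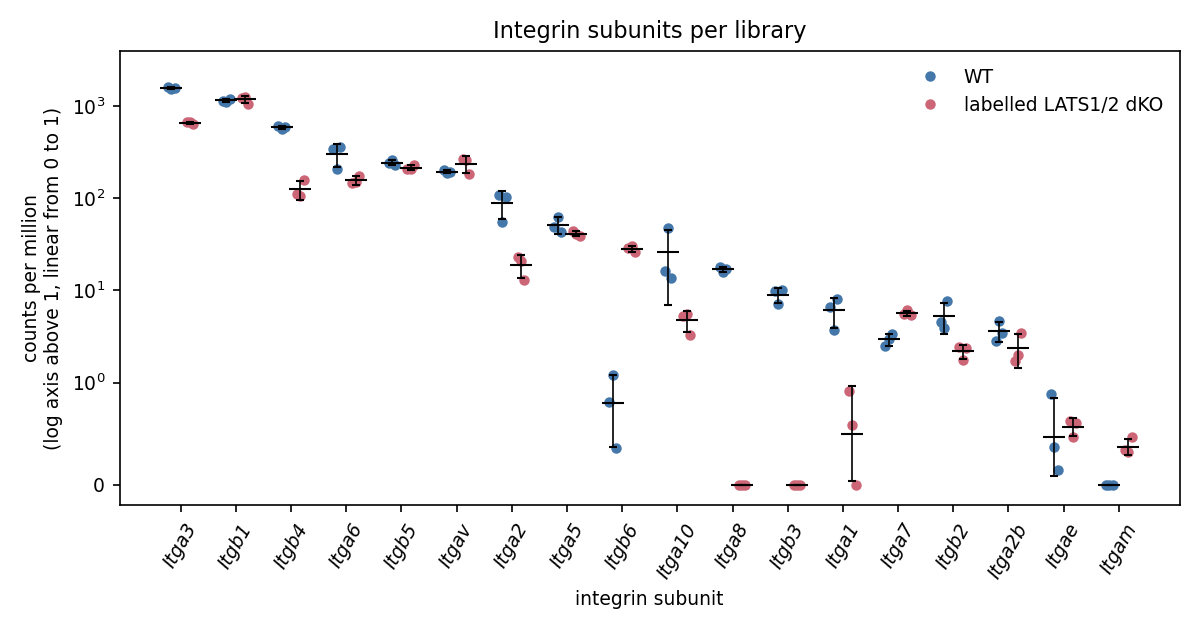
Levels of the 18 tested integrin subunit genes in each library, in CPM, with a log axis above 1 and a linear axis from 0 to 1; points are libraries, and bars are the mean and SD of 3 WT or 3 libraries labelled dKO. Itga3 is lower (659.9 against 1568 CPM) and Itgb6 higher (28.5 against 0.798 CPM) in the libraries labelled dKO, and Itga8 is at 0 there.

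Focal adhesion and contractility genes moved in both directions. Flnc, the gene of the actin cross-linker filamin C, rose from 32.6 ± 5.43 to 272 ± 36.0 CPM, and Src, a tyrosine kinase gene, fell from 149 ± 2.96 to 65.5 ± 4.59 CPM (edgeR adjusted p = 5.25e-07 and 2.51e-06). Of 30 focal adhesion components, 6 rose, 13 fell and 11 did not pass (camera adjusted p = 0.497). Tpm1, a tropomyosin gene, rose from 328 ± 45.6 to 898 ± 41.5 CPM (edgeR adjusted p = 4.35e-06). Of 32 actomyosin contractility genes, 12 rose, 7 fell and 13 did not pass (camera adjusted p = 0.497).

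Of the matrix genes that changed, more fell than rose, while neither matrix list passed the list test. Col18a1, a basement membrane collagen gene, fell from 645 ± 13.9 to 25.5 ± 2.46 CPM, and Lama3, a laminin chain gene, from 114 ± 7.57 to 5.71 ± 0.495 CPM (edgeR adjusted p = 1.05e-08 and 2.18e-08). Of 33 extracellular matrix proteins, 18 fell, 11 rose and 4 did not pass, with a median log2 fold change of -0.56. The list did not pass (camera adjusted p = 0.113). It passed with a stricter count filter (0.0326), with a replicate block (0.0165), without dKO 3 (0.0291) and without WT 2 and dKO 3 (0.000135). Over the camera alternatives its adjusted p ranged from 0.000135 to 0.548. Mmp9, a gelatinase gene, fell from 697 ± 94.8 to 0.282 ± 0.125 CPM, a log2 fold change of -11.27 ± 0.22 (edgeR adjusted p = 1.13e-08). Its levels of 0.419, 0.172 and 0.256 CPM in dKO 1, dKO 2 and dKO 3 were near the floor, so the size of this fold is uncertain. Tgm2, a transglutaminase gene, fell from 170.4 ± 0.901 to 28.8 ± 2.00 CPM (edgeR adjusted p = 5.17e-08). Of 34 matrix-remodelling enzymes and inhibitors, 16 fell, 13 rose and 5 did not pass. That list had a median of 0.05 but a mean of -0.24, with a test direction of lower (camera adjusted p = 0.22). Col18a1 overlaps Slc19a1 and Tgm2 overlaps Rprd1b on the other strand, so their reads cannot be told apart.

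Secreted factors that act on fibroblasts or immune cells also went both ways. Tgfb3, a TGF-beta gene, fell from 149 ± 2.39 to 14.7 ± 1.84 CPM, and Wnt7a, a Wnt ligand gene, rose from 13.8 ± 1.60 to 185 ± 25.4 CPM (edgeR adjusted p = 5.47e-08 and 1.09e-07). Tgfb3 overlaps Gm37804, Gm48008 and Ttll5. Of 22 fibroblast-acting secreted factors, 10 fell, 5 rose and 7 did not pass (camera adjusted p = 0.781). Cx3cl1, the fractalkine gene, fell from 199.7 ± 11.6 to 16.4 ± 2.196 CPM, and Csf3, the gene of granulocyte colony-stimulating factor, from 99.0 ± 6.13 to 10.6 ± 1.48 CPM (edgeR adjusted p = 5.44e-08 and 1.37e-07). Of 19 chemokines and colony-stimulating factors, 7 rose, 7 fell and 5 did not pass (camera adjusted p = 0.644). The median of that list was 0.73 and its mean 0.50, against a test direction of lower, and its median deviation from the WT mean was -0.09 in dKO 3 against 0.68 and 0.72 in dKO 1 and dKO 2.

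Genes of amino acid and unfolded protein stress, and of cholesterol synthesis, were higher in the libraries labelled dKO. Mthfd2, a mitochondrial folate enzyme gene, rose from 11.8 ± 2.43 to 316 ± 5.96 CPM, and Phgdh, which encodes the enzyme of the first step of serine synthesis, from 104 ± 10.2 to 798 ± 29.6 CPM (edgeR adjusted p = 6.02e-08 and 4.74e-08). Of 27 stress genes, 21 rose, 2 fell and 4 did not pass, with a median log2 fold change of 1.27. Ddr2, a collagen receptor gene in that list, rose from 163 ± 16.3 to 305 ± 17.3 CPM and was named after its values were seen. The list passed by camera (adjusted p = 2.24e-09), but not when the correlation was estimated (adjusted p = 0.0893 with an estimated correlation). Mvd, a mevalonate pathway enzyme gene, rose from 14.8 ± 1.302 to 81.7 ± 12.6 CPM, and Msmo1, a sterol oxidase gene, from 95.3 ± 7.11 to 227 ± 4.80 CPM (edgeR adjusted p = 8.87e-07 and 1.76e-06). Of 24 cholesterol synthesis genes, 19 rose, 1 fell and 4 did not pass, with a median of 0.79. That list passed by camera (adjusted p = 0.000343), but not when the correlation was estimated (adjusted p = 0.726 with an estimated correlation).

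Epithelial and mesenchymal genes did not move as blocks. Cgn, the gene of the tight junction protein cingulin, rose from 89.4 ± 6.01 to 332 ± 2.83 CPM, while Epcam, an epithelial adhesion molecule gene, fell from 795 ± 20.6 to 288 ± 15.7 CPM (edgeR adjusted p = 1.49e-07 and 4.68e-07). Of 34 epithelial genes, 14 rose, 10 fell and 10 did not pass, with a median of -0.01, a mean of 0.30 and a test direction of higher (camera adjusted p = 0.497). Pmp22, a myelin protein gene of the mesenchymal list, rose from 0.792 ± 0.117 to 360.1 ± 40.1 CPM, and Gng11, a G protein subunit gene, fell from 26.7 ± 5.07 to 1.06 ± 0.270 CPM (edgeR adjusted p = 5.56e-09 and 7.93e-07). Of 16 mesenchymal genes, 11 fell and 5 rose, with a median of -1.80 (camera adjusted p = 0.595). The mean of that list was -0.08, or -0.48 with genes at 0 set at their bound, with a test direction of lower. The list passed without WT 2 and dKO 3 (0.0233), within a range of 0.0233 to 0.869 over the camera alternatives.

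Hypoxia and glycolysis genes included Ddit4, an mTORC1 inhibitor gene, which fell from 360.5 ± 18.7 to 82.0 ± 8.83 CPM (edgeR adjusted p = 2.85e-07), and Egln3, given above. Of 34 members, 17 rose, 8 fell and 9 did not pass, with a median of 0.44 (camera adjusted p = 0.22), and the list passed with no count filter (0.0419) and without WT 2 and dKO 3 (0.00699), within a range of 0.00699 to 0.726 over the camera alternatives. Ifit2, an interferon-induced gene, rose from 8.69 ± 0.615 to 118 ± 26.8 CPM and Bst2, which encodes tetherin, from 28.7 ± 3.56 to 59.9 ± 4.74 CPM (edgeR adjusted p = 5.35e-07 and 5.78e-05). Of 37 interferon-stimulated genes, 12 rose, 7 fell and 18 did not pass (camera adjusted p = 0.497). The median deviation of that list was -0.38 in WT 2, and -0.12 in dKO 3 against 0.41 in dKO 1 and dKO 2. Ccne1, the cyclin E1 gene, rose from 3.72 ± 0.472 to 13.9 ± 0.564 CPM and Gins2, a replication gene, fell from 55.8 ± 8.53 to 21.7 ± 0.933 CPM (edgeR adjusted p = 1.74e-05 and 1.87e-05). Of 37 cell cycle genes, 9 rose, 7 fell and 21 did not pass (camera adjusted p = 0.881), and their median deviation was -0.39 in WT 2.

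**Figure D3:**
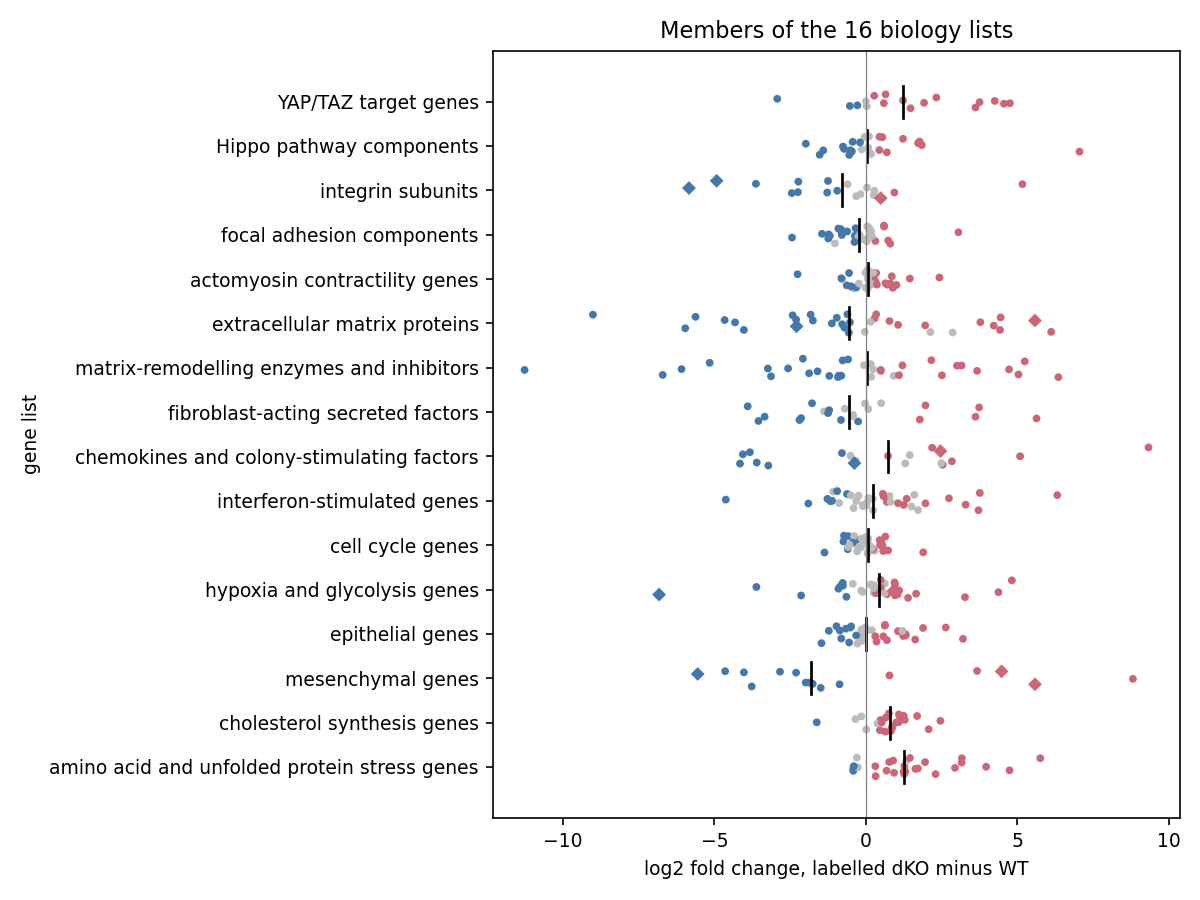
Log2 fold change, libraries labelled dKO minus WT, of each tested member of the 16 biology lists. Red points are genes called higher, blue points genes called lower and grey points genes that did not pass; diamonds are genes at 0 in every library of a group, drawn at the bound from the floor, and black lines are medians. The medians of YAP/TAZ target genes (1.23) and of stress genes (1.27) are the highest.

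Markers of other cell types were low or moved apart. Of 14 fibroblast markers, 6 were tested, of which 2 rose and 3 fell (camera adjusted p = 0.644), and Gsn, the gelsolin gene, rose from 298 ± 9.19 to 913 ± 16.2 CPM. The falls, named after their values were seen, were those of Pdgfra, a growth factor receptor gene, from 38.2 ± 8.53 to 2.399 ± 0.554 CPM, Col1a1, a collagen gene, from 12.1 ± 3.15 to 2.46 ± 0.682 CPM, and Pi16, from 6.198 ± 1.51 to 0.0466 ± 0.0806 CPM (edgeR adjusted p = 1.49e-06, 0.000152 and 6.85e-05). Of 19 macrophage and leukocyte markers, 4 were tested, too few for the list test, of which 2 rose, 1 fell and 1 did not pass, with a median of 0.91. Cd68, a lysosomal protein gene, rose from 2.15 ± 0.207 to 15.6 ± 1.80 CPM (edgeR adjusted p = 2.35e-06). Csf1r, the gene of the receptor for colony-stimulating factor 1, named after its values were seen, rose from 6.25 ± 6.99 to 147 ± 72.9 CPM (edgeR adjusted p = 0.0183), with 62.7 CPM in dKO 3 against 188 and 189.6 CPM in dKO 1 and dKO 2, and 14.2 CPM in WT 2 against 3.55 and 1.01 CPM in WT 1 and WT 3. Its log2 fold change was 4.58 ± 1.09, and 5.99 without WT 2. Without WT 1 the call of Csf1r was lost (edgeR adjusted p = 0.0669), and over the alternatives the adjusted p of Csf1r ranged from 2.44e-05 by DESeq2 to that value. Adgre1, a macrophage marker also named after its values were seen and not tested, was at 2.12 and 2.53 CPM in dKO 1 and dKO 2 and at 0 in the other libraries, in CPM without TMM scaling. Of 15 endothelial and pericyte markers, 7 were tested, of which 2 rose and 2 fell, with a median of 0.39, a mean of -0.35 with genes at 0 set at their bound, and a test direction of lower (camera adjusted p = 0.881). Flt1, a VEGF receptor gene, fell from 22.4 ± 2.07 to 4.25 ± 0.947 CPM. Among 13 mitochondrially encoded mRNAs, 1 rose and 3 fell (camera adjusted p = 0.872), with mt-Cytb at a log2 fold change of -0.37 ± 0.06. Among 48 ribosomal protein genes, 19 rose and 2 fell (camera adjusted p = 0.34), with Rplp1 at 0.96 ± 0.09. Adjusted over the list alone, the counts of called members were the same except for 14 focal adhesion falls, 8 actomyosin falls, 13 matrix protein rises, 18 hypoxia and glycolysis rises, 20 cholesterol synthesis rises, 2 leukocyte marker falls and 18 ribosomal rises.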

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

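Tests on counts divided by 4, with a GC and length correction, and without WT 2 and dKO 3 were chosen only after the result was seen. The 9060 called genes were counted again under 17 alternatives. With each library left out in turn the count ran from 8041 to 9120, and 16 of the 17 counts were within 1.5 times of it, from 7067 (adjusted p under 0.01) to 10139 (without WT 2 and dKO 3). Against a 1.5-fold change, which asks for larger changes by construction, 4556 genes were called. DESeq2 called 9358, and counts divided by 4 and a GC and length correction gave 8628 and 9131. Of the 20 lists, 3 passed, with 3 to 4 when a library was left out. With an estimated correlation 1 passed, with a stricter count filter 5, without WT 2 and dKO 3 7, and by fry, which does not compare a list with other genes, 14. The cause of the other changes was not tested. For genes taken by the naming rule all 810 alternative fits kept direction and side of the threshold. These fits did not include the test against a 1.5-fold change or the threshold of 0.01. Most of these genes had been chosen for a small adjusted p or a large change, which favours this outcome. Csf1r, outside the rule, lost its call without WT 1 (edgeR adjusted p = 0.0669) and at the threshold of 0.01 (edgeR adjusted p = 0.0183). Itgb1, which did not pass, turned from 0.04 to -0.01 without dKO 2. The fold changes of Lats1 and Lats2 ranged from -1.63 to -1.55 and from 1.40 to 1.65 with a library left out.

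Deviations of same-numbered libraries correlated at -0.06, 0.05 and 0.08, so the numbers were not taken to pair samples. With the replicate number as a block, 8658 genes and 4 lists passed, with extracellular matrix proteins added (adjusted p = 0.0165), and Lats1 and Lats2 changed by -1.59 and 1.52. Planned tests on normalized values were not run, since the files used here hold counts. Depth limits levels under 0.242 to 0.314 CPM.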

Other observations

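The lists of the next paragraph were chosen after the genes with the largest changes were seen, so their counts are not independent evidence and no test of these lists is given. Also chosen only after the result was seen were the tests of gene dosage, of leukocytes, fibroblasts and endothelial cells, of library depth, of a shared culture state, of windows of neighbouring genes and of the overlap between WT 2 and dKO 3.

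Several genes that are commonly induced by ERK signalling were lower in the libraries labelled dKO. Ccnd1, the cyclin D1 gene, fell from 1809 ± 213 to 168 ± 34.0 CPM (SD, n = 3), and Dusp6, an ERK phosphatase gene, from 219.6 ± 14.9 to 12.6 ± 1.56 CPM (edgeR adjusted p = 5.39e-07 and 3.28e-08). Etv4 and Etv5, transcription factor genes, fell by 2.96 and 3.46 on the log2 scale, while Epha4 and Dusp5 rose by 2.71 and 1.66. Of the 20 genes listed for this pathway, 13 fell and 4 rose. Caveola genes included Cav1, the caveolin-1 gene, which rose from 10.6 ± 0.968 to 410.5 ± 7.81 CPM, and Cavin2, which rose from 8.498 ± 0.887 to 115 ± 13.6 CPM, while Cavin3 fell by 2.17 on the log2 scale (edgeR adjusted p = 5.56e-09, 7.75e-08 and 3.77e-07). Of 9 caveola components, 5 rose and 3 fell. Sema3e, a guidance ligand gene, rose from 20.7 ± 1.31 to 663 ± 15.3 CPM, and of 11 class 3 semaphorins and receptors 6 rose and 4 fell. Among these rises, Sema3d was at 0 in WT and at 0.862 CPM in the libraries labelled dKO, near the floor, so its direction adds little. Of 12 BEX and TCEAL family genes listed, 4 were tested and rose, Tceal9 from 68.6 ± 4.34 to 1116 ± 59.7 CPM and Bex3 from 64.2 ± 2.12 to 747 ± 38.6 CPM. The other tested members, Tceal7 and Bex2, were at 0 in WT and at 0.820 and 0.419 CPM in the libraries labelled dKO, near the floor. They passed the count filter only through those libraries, so their direction adds little.

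Chromosome medians of the log2 fold change differed, from -0.21 on chromosome 7 to 0.29 on chromosome 16, with an SD of 0.15 against a 95th percentile of 0.0495 for permuted positions (permutation p = 1e-04, the smallest that 10000 permutations can give). GC content and transcript length were argued against as the whole cause, since the SD stayed at 0.149 after their removal (95th percentile 0.0481), while the SD of 0.105 among genes with changes between -1 and 1 (95th percentile 0.0405) decides nothing, as a few strong genes do not move medians over 376 genes or more. Gene dosage of whole chromosomes or large segments may contribute: over 20 chromosomes, split at the middle tested gene, the medians of the 2 parts correlated (Pearson r = 0.544, permutation p = 0.014, Spearman rho = 0.561, permutation p = 0.011), but without chromosomes 16 and 12 it no longer passed (r = 0.398, permutation p = 0.1), so its passing rests on those chromosomes. Windows of 11 neighbouring genes were scanned after GC and length removal, among genes at a log2 CPM of 2.5 or more. With windows that overlapped a stronger one dropped, 1 passed 1.58, the 95th percentile of the maximum over 100 permutations. It lay on GRCm38 chromosome 6 from 15720661 to 21852515, with a median of 2.00. The window held Cav1, Cav2 and Met, a receptor gene that rose from 98.0 ± 3.74 to 472 ± 16.7 CPM. A first run of the chromosome medians and their correlation, limited to genes at a log2 CPM of 2.5 or more, had given an SD of 0.159 and r = 0.614. No DNA was analysed here, and whether copy number or regulation after the knockout underlies these patterns stays open.

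In all, 144 genes were at 0 in every library of one group and at 1 CPM or more in every library of the other, 75 present in the libraries labelled dKO and 69 in WT. Leukocytes, fibroblasts and endothelial cells were argued against, as 0 members of their fixed marker lists were among these genes. Tyrobp, Lum and Kdr were at 0 in every library. Lyz2, Dcn, Cdh5, Ptprc and Fcer1g, the last 2 also abundant in mast cells, reached at most 0.149, 0.276, 0.172, 0.418 and 0.157 CPM. Other markers went both ways: Csf1r, Cd68, Adgre1, Gsn and Mcam were higher in libraries labelled dKO, and Pdgfra, Col1a1, Pi16, Flt1 and Cd14 in WT. Without TMM scaling, Mcam was at 45.9 to 54.3 CPM in WT and 98.6 to 148 CPM in the libraries labelled dKO. Eng was at 53.3 to 57.9 and 65.8 to 82.2 CPM, and Cd14 at 12.7 to 37.4 and 5.18 to 5.88 CPM. The argument therefore rests on the absent or low markers. Reads given to overlapping or similar genes cannot be told apart for 74 of the 144 genes. Of the 144, 51.39% overlapped another gene or shared a name stem, the symbol less its final number and letters. The mean was 61.68% in level-matched called genes (permutation p = 1). This met the bound set in advance for arguing against such reads. However, a count of 0 itself selects against overlap, so that bound was wrong and the test did not decide. The other 70 genes overlapped no annotated gene and shared no such stem with another of the 144. Stems miss some families: Siglecg and Siglec15, both among these 70, belong to the same family but differ in stem. Similar genes outside the 144 were not looked for either, so reads of family members such as Siglecg and Siglec15 stay uncertain. Cell types that these lists do not cover and a difference between clones of the line stay open and were not tested.

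WT 2 stood apart, with 25 genes at 50 CPM or more in WT over 2-fold from both other WT libraries, all 25 higher, against 2 in WT 1 and 3 in WT 3, which argues against sequencing depth. Of these genes 60% deviated in the direction of the libraries labelled dKO (95% exact binomial interval 38.67 to 78.87%), against 43.44% of all genes at that level higher in the libraries labelled dKO than in WT 1 and WT 3, which both comparisons share, so a culture state shared with that difference cannot be told apart from its absence. A share of 60% or less had been set as the bound against such a state, but that interval reaches past 70%, the bound for it. The interval treats the 25 genes of 1 library as independent, which genes that move together are not. For 10 of them the log2 difference of the libraries labelled dKO from WT 1 and WT 3 was within 0.5. Choosing genes on the mean of all 6 libraries had first given 79.31% of 29 genes, but that choice favours genes high in the libraries labelled dKO and was replaced after it was seen. Likewise dKO 3 stood apart, with 29 genes at 50 CPM or more in its group over 2-fold from both other libraries labelled dKO. All 29 were lower, against 1 such gene in dKO 1 and 1 in dKO 2. Of 18 such genes high in WT 2 and 17 low in dKO 3, among 4028 genes at that level in both groups, 10 were the same against 0.076 for independent lists. Among the 10 were the heat shock genes Hspa1a, Hspa1b, Hsph1 and Hspa4l, and Akr1b3.

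Of the 10 splits of the 6 libraries, the real one gave 9060 genes and the highest other 0, and the real one gave 3 lists and the highest other 5. For genes, only 1 split of 10, the real one, gave as many, and 10 splits are too few for a share under 0.05. For lists, 8 of the 10 splits, the real one included, gave at least 3. The number of lists passing therefore does not set the real split apart from the others. Every other split placed both genotypes in each group, unevenly, so it kept part of the genotype difference. The rest of that difference went into the spread within groups. Those splits are thus no background free of genotype, and neither count decides whether the differences arose by chance.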
